A study of Drosophila melanogaster with 12 samples.

How the data were processed

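RNA of Drosophila larvae of 4 groups (control fed, labelled HNF4 mutant fed, control starved for 24 h, labelled HNF4 mutant starved for 24 h) was measured on 12 one-colour Affymetrix arrays, 3 per group. The groups were taken from the sample labels. Replicate arrays were hybridised from samples prepared in triplicate, and the labels do not say what a replicate number shares between groups.

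The main table holds intensity values on a linear scale that the authors normalized with dChip and restricted to probe sets with Present calls, per the file headers; the version, the model, the baseline array and the rule for a Present call are not stated. It has 9669 probe sets, none of them array controls, with array medians of 483 to 552 (fed mean 503, starved mean 543). The series matrix holds the deposited processed intensity of 18769 probe sets after 183 control probe sets are left out; how that signal was computed is not stated, so only its linear scale could be checked. Its array medians were 79.1 to 113, and 19.9% of its values lay under the floor of 16, against 11 of 116028 values in the dChip table. Columns of the dChip table were matched to samples by name, and checked: each of the 12 correlated best, after centring each gene, with its own sample in the other table. Arrays give no read depth, and their number limits the precision.

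Values were raised to a floor of 16 and taken to log2, with no further normalization and no filter on dim probe sets. Probe sets were named through the platform annotation, with symbols updated through the Entrez gene number: 7970 probe sets had 1 symbol, 248 several and 1451 none, and those with several were not named. limma 3.58.1 in R 4.3.3 was fitted with 1 mean per group over all 12 arrays (lmFit, eBayes; 8 residual and 3.12 prior degrees of freedom), and 5 contrasts were taken: mutant minus control in fed and in starved larvae, starved minus fed in controls and in mutants, and the difference between the starvation responses. P-values were adjusted by the Benjamini-Hochberg method over all 9669 probe sets within a contrast, with a threshold of 0.05. Differences are log2 of the floored values with the standard error of the fit. Without adjustment, 1071, 1955, 6924, 7502 and 1693 probe sets had p under 0.05 in these contrasts. The code was tested on simulated data with known changes.

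Gene lists, 31 in all, were written before the data were examined, from general knowledge and with the study's subject, HNF4 in larvae, in mind, but not from any table of the study. They cover mitochondrial β-oxidation, peroxisomal oxidation, acyl-CoA synthetases and fatty acid transport, lipases, lipogenesis and storage, elongases, lipoproteins and lipid carriers, glycolysis, gluconeogenesis and trehalose, amino acid catabolism, the nuclear respiratory chain, mitochondrial DNA transcripts, the tricarboxylic acid cycle, cytochrome P450, glutathione S-transferases with UDP-glycosyltransferases, insulin and FOXO signalling with starvation hormones, autophagy, ribosomal proteins, ribosome biogenesis, digestive proteases, digestive carbohydrases, antimicrobial peptides with peptidoglycan recognition, heat shock proteins, cuticle proteins, ecdysone response, L3 staging, and markers of muscle, neurons and glia, hemocytes, oenocytes with Malpighian tubules, and male germline. Of their 915 genes 581 were measured, 0 of them in the mitochondrial DNA list, which was not tested; 9 genes stood in more than 1 list, and 8 written members were left out because symbol and CG number did not point to the same gene or 1 of them was not found. A gene was represented by its probe set with the highest mean. Members were counted as higher or lower with p adjusted over all probe sets and adjusted over the list alone, and limma's camera (inter-gene correlation 0.01, Benjamini-Hochberg over 30 lists within a contrast) tested each list with at least 5 measured members, again with an estimated correlation.

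Genes to be named were chosen by a rule set before the data were examined: per contrast, among probe sets with 1 symbol past the threshold and with no overlap between the compared arrays (not asked for the difference of responses), the 8 largest rises and 8 largest falls; up to 4 called members of each list with the largest change; any member of a list with fewer than 3 called; and Hnf4. Genes named outside it are said to have been chosen after their values were seen.

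The 5 counts, the named genes and the lists were recomputed with the series matrix, floors of 1 and 64, quantile normalization, median centring, without the dimmest 40% of probe sets, with the replicate number as a block, with eBayes trend and robust (for the lists, a variance trend in the set test), with array weights, with the arrays of the compared groups alone, with a minimum change of 1.5-fold, with the mean of all probe sets of a gene (lists), and without each array in turn. Added after seeing the data were array weights by the gene-by-gene method, leaving out the 2 arrays with the lowest weights (control fed replicate 3 and mutant starved replicate 2), the series matrix restricted to the probe sets of the dChip table, and, for list calls gained in a setting, the correlation estimated in that setting. Other splits of the arrays were refitted (10 for each comparison of 3 with 3 arrays, 100 drawn for the difference of responses). Correlations between contrasts were set beside 100 simulations of unchanged groups with the measured spread. Genotype differences from separate arrays were multiplied over all probe sets, within and between diets, with a standard error from leaving out 1 array at a time. The 3' to 5' ratios of the actin and GAPDH control probe sets came from the series matrix. Positions were taken from the RefSeq annotation of genome release 6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.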

Results

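Transcript levels were measured in Drosophila larvae on 12 one-colour Affymetrix expression arrays, 3 for each of 4 groups. Control larvae carried precise excisions of a pair of P-elements in trans, and larvae labelled HNF4 mutant carried a pair of HNF4 deletion alleles in trans. HNF4 is a nuclear receptor, and the series was made to find the transcripts that depend on it. Late L2 larvae of each genotype were kept on food or starved for 24 h, and RNA was taken from apparently healthy animals that had reached L3. The number of arrays limits the precision, and p-values refer to the spread between these triplicate samples. The median expression value of an array lay between 483 and 552 in the dChip table, which held 9669 probe sets. Replicates of a group correlated at r = 0.968 to 0.994 over the log2 values of these probe sets. The first principal component held 78.6% of the variance and separated starved from fed arrays, as the plot of array scores shows. On the next component, with 6.45% of the variance, control fed replicate 3 scored -9.71 against 15.6 and 11.7 for the other control fed arrays. The mutant fed arrays scored 0.36, -13.9 and -8.01 on it. Starved arrays parted by genotype on this component, with controls at 13.5, 12.6 and 12.9 and mutants at -13.5, -7.10 and -14.4.

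**Figure D1:**
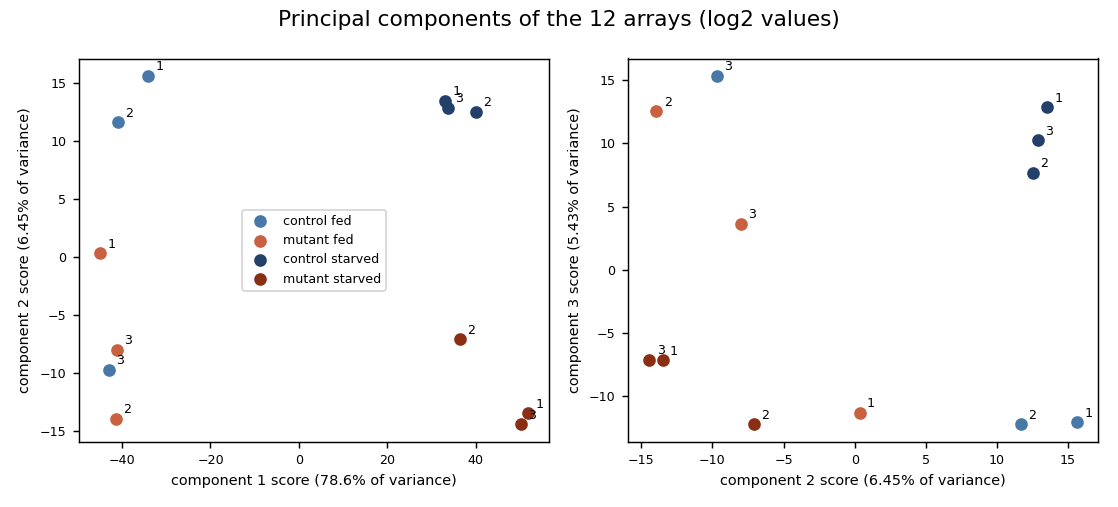
Scores of the 12 arrays on the first 3 principal components of the log2 expression values, with the share of variance on each axis and the replicate number beside each point. Fed and starved arrays lie apart on the first component (78.6% of the variance), and control fed replicate 3 lies with the mutant fed arrays on the next (6.45%).

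The targeted gene was detected in every array. Hnf4 (CG9310, chromosome arm 2L, positions 8687226 to 8709611 of genome release 6) had expression values of 1327, 1207 and 1228 in the control fed arrays and 1641, 1540 and 1482 in the mutant fed arrays. In starved larvae the values were 1736, 1818 and 1937 in controls and 2784, 2938 and 3190 in labelled mutants. Hnf4 was thus higher in every labelled mutant array than in the controls of the same diet. The log2 difference was 0.31 ± 0.080 (SE, n = 3 per group, limma adjusted p = 0.133) in fed larvae and 0.70 ± 0.080 (adjusted p = 0.000396) in starved larvae. In the series matrix, the other table of the same arrays, the fed difference was 1.13 (adjusted p = 0.00447, against 0.0863 to 0.405 in the other settings of the dChip table). Where the probes lie relative to the deletions is not given in the sources at hand, so this probe set does not check the genotype labels, and groups are named below as labelled.

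The first comparison asked which transcripts depended on HNF4 when food was present. In fed larvae labelled mutant, transcripts of mitochondrial fatty acid β-oxidation were lower. Of the 16 measured members of that list, 10 fell and 0 rose (12 and 0 when adjusted over the list alone), with a median log2 difference of -0.835. The fall was 4.14-fold for yip2 (CG4600), the mitochondrial 3-ketoacyl-CoA thiolase, with a mean value of 3347 ± 508 (SD, n = 3) in controls and 812 ± 154 in mutants (log2 -2.05 ± 0.16 SE, adjusted p = 4.9e-05). Acadvl, a very long chain acyl-CoA dehydrogenase, changed by log2 -1.31 ± 0.079, Mtpbeta, a subunit of the trifunctional protein, by -1.30 ± 0.096, and CG4598 by -1.26 ± 0.11. Of 7 measured peroxisomal fatty acid oxidation transcripts, 3 fell and 0 rose (5 and 0 when adjusted over the list alone). They were the acyl-CoA oxidase Acox57D-d (log2 -1.54 ± 0.092), ScpX (-0.97 ± 0.19) and Mfe2 (-0.81 ± 0.16), and CROT, a carnitine octanoyltransferase outside that list, fell as well (-1.62 ± 0.23). Of 11 acyl-CoA synthetases and fatty acid transport proteins, 2 fell, CG6178 (log2 -1.43 ± 0.14) and pdgy (-0.82 ± 0.14), and 0 rose. AkhR, the receptor of adipokinetic hormone, which mobilises stored lipid, was lower by log2 -0.83 ± 0.15.

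Other transcripts with large differences in fed larvae belonged to several classes. CG9289 was higher by log2 3.04 ± 0.16 (adjusted p = 6.77e-06), and LManIII, a lysosomal α-mannosidase, was lower by log2 -2.66 ± 0.38 (adjusted p = 0.00618). These are the 3rd and 7th nearest measured genes of Hnf4 on chromosome arm 2L. The UDP-glycosyltransferase Ugt35C1 rose by log2 1.52 ± 0.090, CG5892 by 1.16 ± 0.17, CG16762 by 1.10 ± 0.13, the cytochrome P450 Cyp6w1 by 1.03 ± 0.16 and the esterase alpha-Est5 by 0.92 ± 0.18. The glutathione S-transferases GstT3 (log2 -1.57 ± 0.21) and GstT1 (-0.76 ± 0.12), the P450 Cyp6a18 (-0.97 ± 0.13), the odorant-binding protein gene Obp56e (-1.82 ± 0.11), CG10962 (-1.96 ± 0.35), CG12951 (-1.73 ± 0.31) and CG17477 (-1.71 ± 0.22) fell. The lower values of CG9289, CG5892, Obp56e, CG12951 and CG17477 lie under the lowest array's 25th percentile of 250.5, so the sizes of these differences are uncertain. The fatty acid elongase gene CG16904 was the 1 of 13 measured elongases that rose (log2 0.76 ± 0.14). The rule for naming the largest changes admits only genes whose values do not overlap between the compared groups.

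In total, 102 of 9669 probe sets passed the threshold between genotypes in fed larvae, 18 higher and 84 lower in labelled mutants, and 78 of them changed at least 1.5-fold. By the set test the β-oxidation list was lower (adjusted p = 1.4e-18, and adjusted p = 0.13 with an estimated correlation), as was the peroxisomal list (3.1e-06, and adjusted p = 0.23 with an estimated correlation). Elongases (adjusted p = 0.0027), glutathione S-transferases (0.014), ribosome biogenesis (0.014) and digestive proteases (0.015) were called higher as sets and insulin signalling lower (0.02), with at most 3 called members each, and none held (adjusted p = 0.36, 0.82, 0.82, 0.82 and 0.33 with an estimated correlation). The count was 272 without control fed replicate 3 and 59, 64, 59 and 47 without control fed replicate 2 and mutant fed replicates 1, 2 and 3. With the series matrix values 63 probe sets passed, and 16 of the 28 genes named for fed larvae kept their direction and lost their call. They were CROT, LManIII, AkhR, ScpX, Mfe2, pdgy, Obp56e, alpha-Est5, CG10962, CG12951, CG16904, CG17477, CG17560, CG5892, Cyp6a18 and GstT1. With the arrays of the compared groups alone 41 passed and 13 of the 28 lost their call, CROT, LManIII, Mfe2, ScpX, AkhR and Cyp6a18 among them. Leaving out 1 array at a time ended the call of 12, Cyp6w1 and GstT1 among them.

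**Figure D2:**
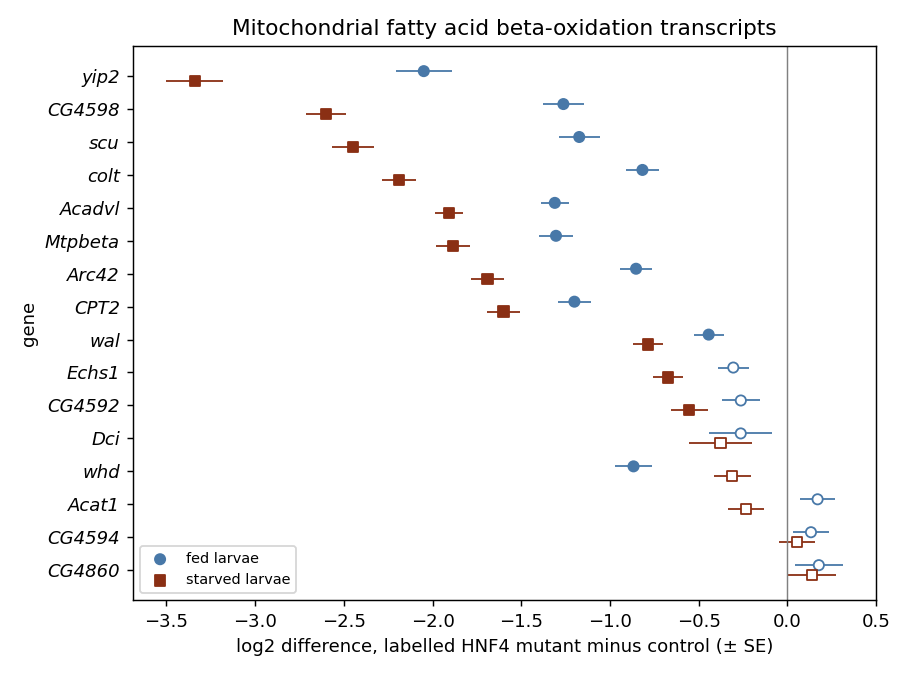
Log2 difference of labelled HNF4 mutant minus control for the 16 measured mitochondrial fatty acid β-oxidation transcripts, in fed (circles) and starved (squares) larvae, with the standard error of the limma fit as bars; filled symbols passed the threshold. yip2 lies at -2.05 in fed and -3.34 in starved larvae, and 10 transcripts fell in fed and 11 in starved larvae.

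The same comparison in starved larvae asked which transcripts depended on HNF4 after 24 h without food. Of the 16 β-oxidation transcripts, 11 fell and 0 rose in labelled mutants (13 and 0 when adjusted over the list alone), with a median log2 difference of -1.19. The fall reached 10.1-fold for yip2 (log2 -3.34 ± 0.16, adjusted p = 2.77e-07), and was log2 -2.60 ± 0.11 for CG4598, -2.45 ± 0.12 for the 3-hydroxyacyl-CoA dehydrogenase scu and -2.19 ± 0.095 for colt, the mitochondrial carnitine/acylcarnitine carrier. Of the 7 peroxisomal transcripts 4 fell and 0 rose (5 and 1 when adjusted over the list alone), Acox57D-d by log2 -1.84 ± 0.092, Mfe2 by -1.40 ± 0.16, Acox3 by -0.93 ± 0.23 and ScpX by -0.82 ± 0.19. Of 14 transcripts of lipogenesis and lipid storage, 8 fell and 0 rose (11 and 0 when adjusted over the list alone). Fatty acid synthase FASN1 was 6.27-fold lower (log2 -2.65 ± 0.13), acetyl-CoA carboxylase ACC changed by log2 -1.33 ± 0.20, the glycerol-3-phosphate acyltransferase mino by -0.64 ± 0.096 and the acetyl-CoA synthetase AcCoAS by -0.57 ± 0.14.

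Acyl-CoA synthetases CG6178 (log2 -2.11 ± 0.14), bgm (-0.75 ± 0.11) and Acsf2 (-0.72 ± 0.13) were the 3 of 11 members of their list that fell in starved larvae, and 0 rose. The elongases sit (2.01-fold lower, SE 0.21 on the log2 scale) and CG16904 (log2 -0.94 ± 0.14) were the 2 of 13 that fell. Among 16 lipid carriers and sterol transport transcripts, 2 rose and 2 fell; the sterol-binding Npc2e fell by 1.65 on the log2 scale (SE 0.24), the fatty acid binding protein gene fabp was 2.31-fold lower (SE 0.22 on the log2 scale), and Npc2b rose by log2 0.64 ± 0.084. Of 12 transcripts of insulin and FOXO signalling and starvation hormones, the stress protein Sestrin (Sesn) rose by log2 0.74 ± 0.10, and AkhR (-0.93 ± 0.15) and the zinc finger gene sugarbabe (sug, -1.18 ± 0.24) fell. Pyruvate carboxylase (PCB, log2 -0.59 ± 0.11) and glutamine synthetase (Gs2, -1.29 ± 0.12) were lower too. CG9577 (log2 -2.69 ± 0.097) and Dhrs4 (-2.29 ± 0.12), which no list held, were among the 8 largest falls.

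Transcripts of detoxification enzymes were higher in starved mutants for part of each list. Of 63 measured cytochrome P450 transcripts, 11 rose and 4 fell (15 and 5 when adjusted over the list alone). Cyp6w1 was 20.4-fold higher (log2 4.35 ± 0.16), Cyp6a8 17.0-fold (4.09 ± 0.17) and Cyp6a2 14.1-fold (3.82 ± 0.21), and Cyp4d14 5.67-fold (SE 0.33 on the log2 scale). Of 56 glutathione S-transferases and UDP-glycosyltransferases, 10 rose and 3 fell (13 and 5 when adjusted over the list alone), with GstD2 at log2 2.01 ± 0.20, Ugt35C1 at 1.88 ± 0.090 and GstT3 at -2.51 ± 0.21. Probe sets of such closely related genes can bind each other's transcripts, so single members of the Cyp6a and GstD groups are uncertain. CG9289 was higher by log2 5.87 ± 0.16 (adjusted p = 7.32e-09), at 1906 ± 360 (SD, n = 3) against 32.3 ± 3.59 in controls. Those control values lie under the lowest array's 25th percentile of 250.5, so the size of this difference depends on the floor (log2 4.88 with a floor of 64). CG2065 (2.79 ± 0.30), Jig (2.55 ± 0.49) and CG6908 (2.40 ± 0.35) were higher as well. Control values of CG2065 and mutant values of GstT3 are dim by the same measure.

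Some autophagy transcripts rose and some cuticle protein and hemocyte transcripts fell in starved mutants. Of 14 autophagy transcripts, 5 rose and 0 fell (6 and 0 when adjusted over the list alone), among them the protease gene Atg4a (log2 0.57 ± 0.066), Atg18a (0.52 ± 0.072) and the kinase gene Atg1 (0.43 ± 0.10). Of 75 larval cuticle protein transcripts, 2 rose and 11 fell (2 and 18 when adjusted over the list alone), Lcp65Af by log2 -2.26 ± 0.50 (-2.91 without control starved replicate 2) and Cpr67Fa2 by -1.89 ± 0.39. Of 9 hemocyte markers 3 fell and 0 rose (8 and 0 when adjusted over the list alone), namely the collagen IV genes vkg (log2 -0.72 ± 0.13) and Col4a1 (-0.51 ± 0.10), which fat body also expresses, and peroxidasin (Pxn, -0.41 ± 0.11). The recognition protein gene PGRP-LB rose (log2 0.99 ± 0.20), the 1 call among 21 transcripts of antimicrobial peptides and peptidoglycan recognition. CG10073 was lower by log2 -2.36 ± 0.30. The lower values of CG10073, PGRP-LB, Acox57D-d, CG16904 and sug were dim too.

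In total, 736 of 9669 probe sets passed the threshold in starved larvae, 378 higher and 358 lower in labelled mutants, and 357 changed at least 1.5-fold, 138 higher and 219 lower. By the set test, lists were lower for β-oxidation (adjusted p = 2.1e-20) and lipogenesis (2.1e-07), and both calls held with an estimated correlation (adjusted p = 0.048 for each). The calls of the peroxisomal list (adjusted p = 0.00064), acyl-CoA synthetases (0.0028), elongases (0.012), cuticle proteins (2.2e-06), hemocyte markers (8e-05), male germline markers (0.0011, with 1 of 8 called), P450s (0.012, higher) and autophagy (5.5e-06, higher) did not hold (adjusted p = 0.37, 0.44, 0.44, 0.47, 0.37, 0.47, 0.80 and 0.11 with an estimated correlation). The glutathione S-transferase and UDP-glycosyltransferase list was not called as a set (adjusted p = 0.22). The count was 329, 358, 406 and 363 without control starved replicates 1 and 3 and mutant starved replicates 1 and 3. It rose to 2439 with array weights (1131 higher and 1308 lower) and to 1230 without the 2 low-weight arrays (564 and 666). With the series matrix values 376 probe sets passed, and 12 of the 48 genes named for starved larvae lost their call with no change of direction: AcCoAS, Acox3, AkhR, Atg1, Col4a1, Cpr67Fa2, Lcp65Af, Pxn, ScpX, Sesn, sit and sug. Leaving out 1 array at a time ended the call of 11 of the 48. They were AcCoAS, Acox3, Atg1, Col4a1, Cpr67Fa2, Lcp65Af, PGRP-LB, Pxn, ScpX, sit and sug.

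**Figure D3:**
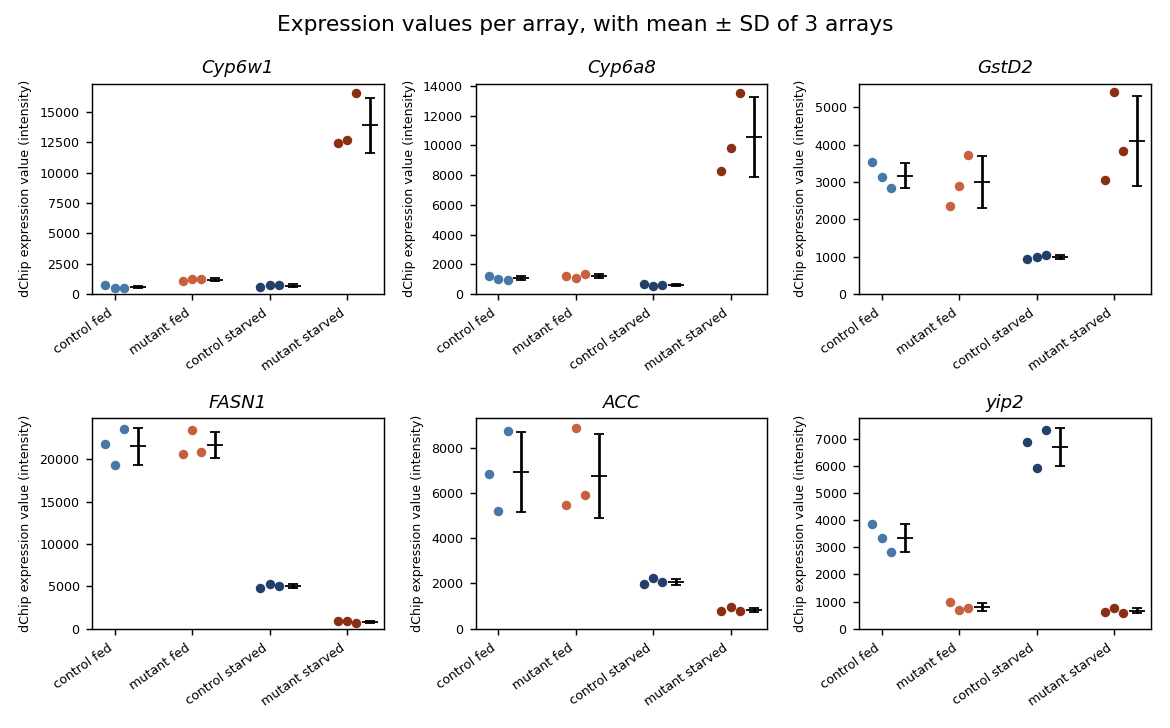
dChip expression values (intensity, linear scale starting at 0) of 6 genes in each of the 12 arrays, with the mean and SD of the 3 arrays of a group. Cyp6w1, Cyp6a8 and GstD2 are higher in starved mutants than in starved controls, while FASN1, ACC and yip2 are lower, and yip2 is also lower in fed mutants.

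Starved and fed controls were compared to describe the response to 24 h without food when HNF4 was intact. Over all probe sets 68.2% passed the threshold in this comparison. A list with a share of called members near that does not stand out by its count. Of 15 lipases 9 rose and 3 fell (9 and 3 when adjusted over the list alone), with a median of log2 1.336 that was 0.254 in the series matrix. Among those that rose were Lip3 (44.4-fold, log2 5.47 ± 0.18, adjusted p = 1.04e-08), CG6271 (log2 4.11 ± 0.18), CG8093 (3.34 ± 0.51, or 2.65 without control fed replicate 3) and brummer (bmm, 3.10 ± 0.16), the triglyceride lipase of the lipid droplet. Of the 14 transcripts of lipogenesis and storage, 3 rose and 7 fell (3 and 8 when adjusted over the list alone), with FASN1 at log2 -2.10 ± 0.13, AcCoAS at -2.08 ± 0.14, the perilipin gene Lsd-1 at -2.26 ± 0.16 and Lipin (Lpin) at 1.70 ± 0.14. β-oxidation transcripts went both ways, 4 higher and 4 lower of 16, among them the carnitine palmitoyltransferase whd (log2 2.03 ± 0.10), yip2 (1.01 ± 0.16) and CG4594 (-1.50 ± 0.10). Of 9 gluconeogenesis and trehalose transcripts, 6 rose and 2 fell, including the phosphoenolpyruvate carboxykinases Pepck2 (log2 2.32 ± 0.29) and Pepck1 (1.61 ± 0.22).

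Autophagy transcripts rose in starved controls, 11 of 14 with 0 lower, including Atg101 (log2 2.08 ± 0.17), Atg9 (1.67 ± 0.14), ref(2)P (1.45 ± 0.11) and Atg1 (1.37 ± 0.10). Of 12 transcripts of insulin and FOXO signalling 9 rose and 2 fell, with Lip4 at log2 2.63 ± 0.21, the pyruvate dehydrogenase kinase Pdk at 1.78 ± 0.15, Sesn at 1.48 ± 0.10 and sug at -1.56 ± 0.24. Nuclear respiratory chain and ATP synthase transcripts were lower, 45 of 56 with 4 higher (46 and 4 when adjusted over the list alone), at a median of log2 -0.439, for example ND-15 (-0.82 ± 0.12) and COX7C (-0.72 ± 0.084). Of 21 transcripts of antimicrobial peptides and peptidoglycan recognition 15 rose and 1 fell, including the Bomanins BomS6 (log2 4.18 ± 0.41) and BomS2 (4.78 ± 1.12, but 6.16 and 3.92 without control fed replicates 1 and 3), members of a family of similar sequence. Hemocyte markers fell, 7 of 9 with 0 higher, including the prophenoloxidases PPO1 (log2 -1.95 ± 0.29) and PPO2 (-1.35 ± 0.25), and cuticle protein transcripts fell more often than they rose, 36 against 7 of 75, for example Lcp65Ae (-2.86 ± 0.40) and Cpr51A (-2.33 ± 0.18).

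P450 transcripts rose in 30 and fell in 10 of 63 in starved controls, with Cyp4ac3 at log2 3.12 ± 0.20 and Cyp310a1 at -3.48 ± 0.097. Glutathione S-transferases and UDP-glycosyltransferases fell in 30 and rose in 13 of 56, with GstD4 at log2 -3.50 ± 0.42 and GstD6 at -2.95 ± 0.26. Of 16 amino acid catabolism transcripts 7 rose and 4 fell, and the list's median changed sign in the series matrix. Those that rose included glycine N-methyltransferase (Gnmt, log2 2.38 ± 0.11), GstZ2 (2.32 ± 0.17), homogentisate dioxygenase (hgo, 2.30 ± 0.20) and sarcosine dehydrogenase (Sardh, 1.94 ± 0.15). Of 16 digestive carbohydrases 10 rose and 4 fell, with the amylase-related Amyrel at log2 3.57 ± 0.25 and the maltase Mal-B2 at 2.34 ± 0.12. Large falls were those of the odorant-binding protein gene Obp99b (log2 -6.09 ± 1.42, adjusted p = 0.003, and -5.38, -5.30 and -7.60 without control fed replicates 1, 2 and 3), CG11892 (-5.15 ± 0.29), CG15155 (-4.69 ± 0.24), CG9259 (-4.66 ± 0.24) and CG14258 (-4.58 ± 0.39). Starved values of these 5 genes and of Cyp310a1, GstD4 and GstD6 lie under 250.5, so the sizes of their falls are uncertain. Large rises outside the lists were those of CG14237 (log2 5.03 ± 0.47, or 4.34 without control fed replicate 3), CG5550 (4.64 ± 0.30), CG12951 (4.07 ± 0.31) and Bace (3.98 ± 0.30). Fed values were as dim for CG5550, Lip3 and BomS6.

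In total, 6594 of 9669 probe sets passed the threshold in controls, 3486 higher and 3108 lower after starvation, and 3364 changed at least 1.5-fold. The sample titles give L3 for both diets and no finer stage, so starvation and progress within L3 are not separated. The set test called the respiratory chain list (adjusted p = 6.5e-08, lower), autophagy (0.00017, higher), cuticle proteins (0.0019, lower), antimicrobial peptides (0.013, higher), glutathione S-transferases (0.033, lower) and hemocyte markers (0.033, lower), and none of these held with an estimated correlation (adjusted p = 0.88, 0.58, 0.88, 0.88, 0.88 and 0.88). The lists of lipases (adjusted p = 0.14), lipogenesis (0.14), P450s (0.11) and insulin signalling (0.054) were not called as sets. Those of gluconeogenesis, amino acid catabolism and digestive carbohydrases were not called either. The series matrix called lipogenesis lower (0.0023). Quantile normalization (0.046) and median centring (0.039) called insulin signalling higher. None of these 3 calls held with an estimated correlation (adjusted p = 0.18, 0.81 and 0.85), a setting chosen after seeing the data. The GAPDH 3' to 5' signal ratio was higher in the 6 starved than in the 6 fed arrays (log2 1.21 against 0.662). The difference was 0.544 (exact two-sided permutation p = 0.00216 over 924 regroupings). For the actin ratio the difference was 0.0657 (exact two-sided permutation p = 0.258 over 924 regroupings). A change of RNA quality as a whole is not shown by GAPDH alone, and the cause of its shift was not tested.

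The starvation response of labelled mutants was measured in the same way. In this comparison 75.7% of all probe sets passed the threshold. Lip3 rose by log2 5.47 ± 0.18, CG12951 by 5.67 ± 0.31, CG14237 by 4.83 ± 0.47, CG6271 by 4.24 ± 0.18 and bmm by 3.13 ± 0.16. Of the 16 β-oxidation transcripts 1 rose and 10 fell (the same numbers when adjusted over the list alone), with whd at log2 2.59 ± 0.10, scu at -1.26 ± 0.12 and CG4598 at -1.19 ± 0.11. Of the 14 lipogenesis and storage transcripts 3 rose and 10 fell, with FASN1 at log2 -4.76 ± 0.13 (27.0-fold, adjusted p = 2.43e-09), ACC at -3.00 ± 0.20, AcCoAS at -2.85 ± 0.14 and Lsd-1 at -2.36 ± 0.16. Of 13 elongases 2 rose and 9 fell, with CG8534 at log2 -3.19 ± 0.25.

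Autophagy transcripts rose in 13 of 14 with 0 lower in mutants, including Atg9 (log2 2.34 ± 0.14) and Atg18a (1.86 ± 0.072), and insulin and FOXO signalling transcripts rose in 9 and fell in 3 of 12, with Sesn at 2.26 ± 0.10. P450 transcripts rose in 32 and fell in 8 of 63, with Cyp4ac3 at log2 4.16 ± 0.20 and the mean value of Cyp6a2 at 352 in fed and 5797 in starved mutants. Glutathione S-transferases and UDP-glycosyltransferases rose in 10 and fell in 30 of 56. Respiratory chain transcripts rose in 4 and fell in 45 of 56. Antimicrobial peptides and recognition proteins rose in 14 and fell in 1 of 21, with BomS2 at log2 4.01 ± 1.12 (3.24 and 5.10 without mutant fed replicates 1 and 2). Cuticle protein transcripts rose in 3 and fell in 52 of 75, among them Cpr67Fa1 (log2 -5.08 ± 0.42), Lcp65Af (-4.89 ± 0.50) and Lcp65Ae (-4.83 ± 0.40). Hemocyte markers fell in 8 of 9 with 0 higher, with PPO1 at log2 -2.49 ± 0.29 and vkg at -1.21 ± 0.13. Pepck1 (log2 1.47 ± 0.22), Gnmt (2.53 ± 0.11), the acyl-CoA oxidase Acox57D-p (1.54 ± 0.23), pdgy (5.66-fold) and Bace (log2 4.18 ± 0.30) rose as well. Falls were those of CG11892 (log2 -4.70 ± 0.29), CG9259 (-4.66 ± 0.24), AANATL4 (-4.52 ± 0.42, or -5.12 without mutant starved replicate 2) and CG13360 (-4.28 ± 0.34). Sizes are uncertain where values were dim: CG11892, CG9259, AANATL4 and CG8534 when starved, and Lip3, CG12951, CG14237, Bace and Cyp4ac3 when fed.

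In total, 7322 probe sets passed the threshold in labelled mutants, 3622 higher and 3700 lower after starvation, and 4222 changed at least 1.5-fold. Probe sets that rose in both genotypes numbered 3143 and those that fell in both 2843, where independent lists of these sizes would share 1310 and 1190, and 14 and 10 went opposite ways. The set test called β-oxidation (adjusted p = 0.0046, lower), lipogenesis (0.03, lower), elongases (0.047, lower), respiratory chain (1.8e-06, lower), P450s (0.012, higher), glutathione S-transferases (0.048, lower), insulin signalling (0.047, higher), autophagy (2.6e-05, higher), antimicrobial peptides (0.012, higher), cuticle proteins (2.9e-06, lower) and hemocyte markers (0.0046, lower). With an estimated correlation none was called (adjusted p = 0.61, 0.58, 0.61, 0.58, 0.83, 0.91, 0.58, 0.42, 0.58, 0.58 and 0.58). The GAPDH 3' to 5' ratio, higher in starved arrays by 0.544 on the log2 scale, moved with this comparison too.

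**Figure D4:**
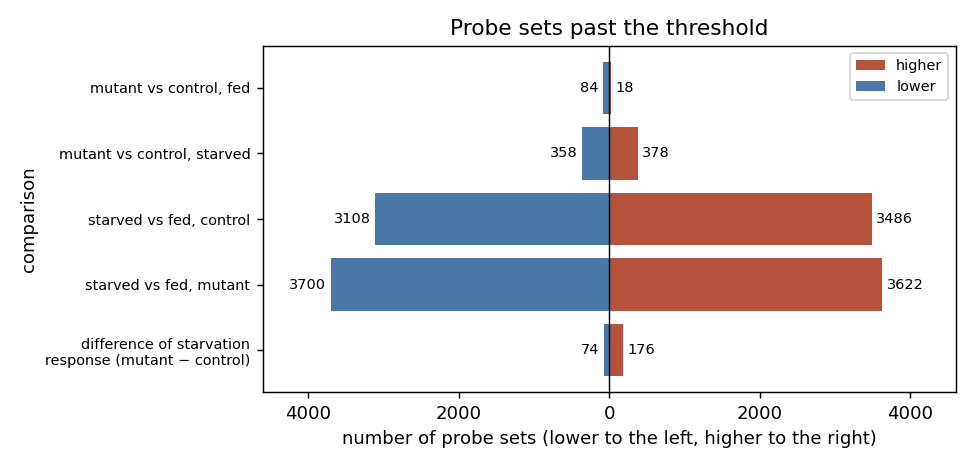
Number of probe sets past the threshold in each of the 5 comparisons, lower to the left and higher to the right of 0, out of 9669 tested. Starved and fed larvae differed in 6594 probe sets in controls and in 7322 in labelled mutants, while the genotypes differed in 102 when fed and in 736 when starved.

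Whether starvation acted differently in the genotypes was tested by the difference between the responses. A higher response can come from a rise in mutants, from a fall in controls or from both. Detoxification transcripts led the positive differences: the response was higher in labelled mutants by log2 3.94 ± 0.24 for Cyp6a8 (adjusted p = 3.16e-05), 3.46 ± 0.30 for Cyp6a2, 3.33 ± 0.23 for Cyp6w1, 2.18 ± 0.46 for Cyp4d14, 2.11 ± 0.28 for GstD2 and 1.90 ± 0.16 for GstD3. Of 63 P450 transcripts 8 had a higher and 1, Cyp4e3 (log2 -1.80 ± 0.39), a lower response (12 and 4 when adjusted over the list alone), and of 56 glutathione S-transferases and UDP-glycosyltransferases 4 were higher and 0 lower (7 and 5 when adjusted over the list alone). Of 16 β-oxidation transcripts 7 had a lower and 0 a higher response (11 and 1 when adjusted over the list alone), with colt at log2 -1.37 ± 0.13, CG4598 at -1.34 ± 0.16, yip2 at -1.29 ± 0.23 and scu at -1.28 ± 0.16. The mean value of yip2 was 3347 in fed and 6704 in starved controls, and 812 in fed and 664 in starved mutants. Values of GstD2 were 3529, 3123 and 2851 in fed and 946, 1001 and 1032 in starved controls. In mutants GstD2 values were 2349, 2903 and 3735 when fed and 3063, 5410 and 3825 when starved, with overlap. Cyp6a8, GstD3, Cyp4d14, CG2065 and CG6908 were also lower in every starved than in every fed control array.

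FASN1 fell further in mutants than in controls, by log2 -2.66 ± 0.19 more (adjusted p = 5.79e-05). It differed by 0.012 between the genotypes when fed. ACC (log2 -1.30 ± 0.29) and the isocitrate dehydrogenase Idh (-0.68 ± 0.14) were the other 2 of 14 lipogenesis transcripts with a lower response (0 higher, and 5 lower when adjusted over the list alone), and the elongase CG16904 (-1.70 ± 0.20) and the acyl-CoA synthetase Acsf2 (-1.17 ± 0.19) had lower responses too. Autophagy transcripts Atg4a (log2 0.73 ± 0.093), Atg18a (0.66 ± 0.10) and Atg16 (0.45 ± 0.10) were the 3 of 14 with a higher response (6 when adjusted over the list alone, 0 lower), and Sesn rose further in mutants (0.78 ± 0.14). CG9289 (log2 2.84 ± 0.23), CG6908 (2.32 ± 0.49) and CG2065 (2.28 ± 0.42) had higher responses. Lower responses were those of CG10081 (log2 -3.45 ± 0.45), CG10073 (-3.13 ± 0.43), CG10814 (-1.85 ± 0.43), Gs2 (-1.25 ± 0.17), the collagen gene vkg (-0.84 ± 0.18) and the cuticle protein genes Cpr67Fa1 (-2.96 ± 0.59) and Cpr78Cc (-1.93 ± 0.32). The lowest group of CG9289, CG2065, CG10081, CG10073, CG10814, Cyp4e3 and CG16904 was dim. Of 75 cuticle protein transcripts 2 had a higher and 4 a lower response (3 and 10 when adjusted over the list alone).

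In total, 250 of 9669 probe sets differed in their response, 176 with a higher and 74 with a lower value in labelled mutants, and 129 of the 176 rose in both genotypes. That balance depends on the setting: 656 were higher and 552 lower with array weights, 433 and 367 without the 2 low-weight arrays, and 131 and 88 with median centring. The set test called β-oxidation (adjusted p = 7.7e-09, lower), autophagy (1.3e-05, higher), cuticle proteins (5.4e-07, lower), lipogenesis (1e-04, lower), elongases (1e-04, lower), digestive proteases (0.0076, lower, with 1 of 24 called), hemocyte markers (0.014, lower, with 1 of 9 called) and P450s (0.034, higher), and none held with an estimated correlation (adjusted p = 0.20, 0.18, 0.57, 0.18, 0.20, 0.87, 0.72 and 0.87). The count was 549 without control fed replicate 3 and 447 without mutant starved replicate 2. With the replicate number as a block it was 132, and 9 of the 30 genes named for this test lost their call. These were ACC, Atg16, CG10814, CG6908, Cpr67Fa1, Cyp4d14, Cyp4e3, Idh and vkg. Fits without 1 array at a time ended the call of 12 of the 30, these 9 and CG2065, Sesn and yip2. Leaving out control fed replicates 1 or 2 gave 132 and 125, mutant fed replicates 1 to 3 gave 140, 113 and 88, control starved replicates 1 or 3 gave 85 and 88, and mutant starved replicates 1 or 3 gave 113 and 81. With the series matrix values 26 probe sets passed, 20 of them among the 250, and of the 30 genes named for this test 10 kept their call: Cyp6a8, Cyp6a2, Cyp6w1, GstD2, GstD3, FASN1, CG16904, colt, scu and Gs2.

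The genotype difference in fed larvae was set against that in starved larvae, which shares no array with it. Of the 84 probe sets lower in fed mutants 59 were also lower in starved mutants, where independent lists would share 3.11, and of the 18 higher ones 8 were higher in both (0.704 for independent lists). Among these shared genes were yip2, CG4598, Acox57D-d and GstT3 on the lower side and CG9289, Ugt35C1 and Cyp6w1 on the higher side. Over all 9669 probe sets, which are not independent replicates, the differences correlated at Pearson r = 0.179 and Spearman rho = -0.0504. Simulated unchanged groups gave means of -0.004 and -0.001. Their probe sets varied independently, while probe sets of the measured arrays vary together. The simulation therefore does not show how far r would stray from 0 without a shared genotype effect.

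The genotype difference in fed larvae and the starvation response of controls share the 3 control fed arrays. Of the 84 probe sets lower in fed mutants, 36 rose and 21 fell in starved controls, where independent lists would share 30.3 and 27.0. Pearson's r across probe sets was -0.0407 and Spearman's rho -0.144. Unchanged groups simulated with the shared arrays gave r = 0.503. The simulated groups held no starvation changes, while 68.2% of the measured probe sets passed the threshold in controls. The 2 values of r are therefore not directly comparable. The covariance was -0.00721 against 0.0155 in the simulation. The 3 shared arrays are too few to be split into parts of 2 or more, and the sign of r turned without control fed replicates 1 or 3 or mutant fed replicate 1 (0.0876, 0.0456 and 0.0293) and in the series matrix (0.178).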

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

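The tests of the wider spread, of the same effect in both diets, of the amount of mitochondria and of a constitutive strain difference were chosen after the results were seen; those of chromosome 2, of the neighbours of Hnf4, of the axis among fed arrays and of other splits were written before. The starvation response differed between genotypes, by the test of the difference itself, in 250 probe sets. Other splits of the arrays within each diet gave as many in 2 of 100 drawn splits, the real one included. The highest other split gave 270, more than the real one. It set control fed replicates 1 and 2 and mutant fed replicate 1 against the other fed arrays. Splits that mix the genotypes take real genotype differences into their spread, which lowers their counts. The small share therefore argues only against the absence of any genotype difference. Whether the 2 responses are equal is not tested by these splits. The same parting of the fed arrays gave 948 probe sets against 102 for the genotypes, which points to a structure of the fed samples.

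By the same test the response was higher in labelled mutants for Cyp6a8 (log2 3.94), Cyp6a2 (3.46), Cyp6w1 (3.33), CG9289 (2.84, from dim control values), CG6908 (2.32), CG2065 (2.28), Cyp4d14 (2.18), GstD2 (2.11), GstD3 (1.90), Sesn (0.78), Atg4a (0.73), Atg18a (0.66) and Atg16 (0.45). It was lower for CG10081 (log2 -3.45), CG10073 (-3.13), Cpr67Fa1 (-2.96), FASN1 (-2.66), Cpr78Cc (-1.93), CG10814 (-1.85), Cyp4e3 (-1.80), CG16904 (-1.70), colt (-1.37), CG4598 (-1.34), ACC (-1.30), yip2 (-1.29), scu (-1.28), Gs2 (-1.25), Acsf2 (-1.17), vkg (-0.84) and Idh (-0.68). Of these 30 genes 12 lost their call when 1 array at a time was left out, and 20 lost it with the series matrix values.

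Probe sets that only the series matrix holds, 9100 in number, carried genotype signal too: 9 were higher and 7 lower in fed mutants, and 34 higher and 40 lower in starved mutants. Single genes among them, chosen after their values were seen, were Amacr (log2 -2.28 ± 0.18 in fed and -3.19 ± 0.18 in starved mutants), Pex14 (-0.86 ± 0.13 and -1.30 ± 0.13) and, in starved mutants, Keap1 (1.71 ± 0.25) and ImpL2 (1.29 ± 0.21). No gene list was tested on these probe sets alone.

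The genotypes differed in more probe sets, and β-oxidation transcripts by more, in starved than in fed larvae. Over the 16 β-oxidation members the genotype difference in starved minus that in fed larvae averaged log2 -0.548 ± 0.098 (SE over arrays). That argues against an equal effect in both diets. Over the 7 peroxisomal members it was -0.035 ± 0.202, but members shifted opposite ways, so this mean does not show an equal effect for each. Acox57D-p was lower in fed mutants (550, 450 and 601 against 1234, 919 and 704 in controls). It overlapped its controls when starved (1106, 1632.5 and 2023 against 1358, 1329 and 1629). Mfe2 differed by more when starved. The respiratory chain list had a median of -0.008 in starved and 0.024 in fed mutants (SE of the list mean over arrays 0.038 in each). It stayed above the bounds of -0.298 and -0.209, set after the results were seen for a lower amount of mitochondria. In the series matrix the set test called it lower in fed mutants (-0.091, adjusted p = 0.00028, but 0.56 with an estimated correlation). There it cleared its bound by more than 2 SE of the list mean (0.069) in starved larvae alone (0.023). Nuclear transcripts do not measure the amount of mitochondria, and no mitochondrial DNA transcript was measured, so that explanation stays undecided. The dChip values show only that respiratory chain transcripts did not fall along with those of β-oxidation. The fed arrays had a wider spread (median within-group SD 0.157 and 0.116 against 0.0884 and 0.111 in starved arrays). The fit gives both comparisons the same standard error, but the fed spread enters it. Without control fed replicate 3 the counts were 272 in fed and 909 in starved larvae, against 102 and 736 with all arrays. With the compared arrays alone they were 41 and 905. The fed spread is therefore not excluded as a part of the gap between the counts. Genotype differences from separate arrays were multiplied over all probe sets, a product that independent noise does not raise. Its mean was 0.0908 within starved larvae and 0.0136 between diets. This gap of 0.0772 (SE 0.0311) argues against the same effect in both diets, but effects of equal size on different probe sets would give it too. The value within fed larvae was imprecise (0.0127, SE 0.0516). The starved value exceeded the fed value by 0.0781 (SE 0.0602), under 2 SE, so these products do not show a larger effect in starved larvae. A stronger need of β-oxidation transcripts for HNF4 during starvation is a candidate explanation, untested here, which restoring HNF4 in mutants of both diets and measuring the rescue of each transcript would test.

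Genotype differences could come from strain background rather than from HNF4. Called genes lay on chromosome 2, which carries Hnf4, no more often than others (38.1% of 653 against 38.8% of 6759; odds ratio 0.971, 95% interval 0.820 to 1.15, Fisher's exact p = 0.737). Close to Hnf4, however, 5 of the 100 nearest measured genes were called in both diets against 58 of 7311 others (Fisher's exact p = 0.00153), and 15% of them against 8.71% of others were called in either diet (p = 0.0474), as differences linked to the locus would give: Trs23, the nearest (log2 -0.92 in fed and -1.24 in starved mutants), CG9289 (3.04 and 5.87), LManIII (-2.66 and -1.51), SLC5A11 (-0.57 and -1.46) and Sirup (-1.18 and -2.03), of which Trs23, SLC5A11 and Sirup are named for this count alone. The 21 P450, glutathione S-transferase and UDP-glycosyltransferase genes higher in starved mutants were compared between diets. Their median difference was log2 0.059 in fed against 1.60 in starved larvae. That argues against a constitutive strain difference for most of them, with the reserve that they were picked by their starved call. But 2 were called higher in fed mutants too, Cyp6w1 (1.03 against 4.35) and Ugt35C1 (1.52 against 1.88), the latter as a constitutive difference would give. The fed call of Cyp6w1 did not hold in every fit that left out 1 array. Loss of HNF4 stays the explanation the design names, untested here by a second allele pair or a rescue.

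The 6 fed arrays differed among themselves along 1 axis with 59.9% of their within-group variance, from 25.1 for control fed replicate 3, with mutant fed replicate 2 next, to -14.4 and -14.7 for control fed replicate 1 and mutant fed replicate 1. The median loading of the L3 staging list lay at percentile 1.23 of random lists, as larval age could give, and that of the cuticle list at percentile 100, as moulting state could give. Neither is specific, since lipases (-0.0194), carbohydrases (-0.0173) and ribosome biogenesis (0.0224) had larger median loadings. RNA degradation cannot be told apart from these: the axis followed the GAPDH 3' to 5' ratio at r = 0.784 (exact permutation p = 0.0472, adjusted 0.0944 over 2 ratios; Spearman rho = 0.429, p = 0.419), which rests on the 2 farthest arrays (0.121 without them), and the actin ratio gave r = 0.312 (p = 0.532).

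For the other counts the splits are too few to give a share under 0.05: 2 of 10 splits of the fed arrays gave at least the real 102, while the real split was the 1 of 10 with the highest count in starved larvae (736, highest other 19), in controls (6594, highest other 0) and in mutants (7322, highest other 0).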

How the results depend on the processing

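Array weights by the gene-by-gene method, the fit without the 2 low-weight arrays and the series matrix restricted to the dChip probe sets were chosen after seeing the data. Of 196 named gene results 143 kept direction and call under every planned setting and 0 reversed anywhere. All named starvation genes (57 in controls, 33 in mutants) kept both under every setting run in which they were tested. The genes were named because they passed in the main setting, many as its largest changes, so 0 reversals says little about stability. Of 42 list calls 2 held throughout the planned settings, β-oxidation and lipogenesis in starved larvae, and 40 lost their call with an estimated correlation; digestive proteases in fed larvae reversed (median log2 0.063 to -0.034) without control fed replicate 3, alone or with the other low-weight array, and reached 0.262 without control fed replicate 1; leaving out 1 array ended a list call in 33 of 504 cases, and the filter on dim probe sets in 10. Lists not called otherwise were called 16 times with the series matrix (9 on the dChip probe sets), 4 with quantile normalization, 1 with median centring, 5 without the 2 arrays and up to 7 (without control fed replicate 3) leaving out 1, and with a correlation estimated in the same values, also chosen after seeing the data, none of these held (adjusted p = 0.12 or more). Floors of 1 and 64, quantile normalization, median centring and eBayes with trend and robust left all 5 counts within 1.5 times the main ones. Fed genotype count (102): 63 with the series matrix, 193 with array weights, which stopped before reaching their tolerance, 172 gene by gene, 41 with the compared arrays alone, 292 without the 2 low-weight arrays, and 47 to 272 without 1 array. Starved genotype count (736): 376 with the series matrix (388 on the dChip probe sets), 2439 and 2364 with the weights, 357 at 1.5-fold, 1230 without the 2 arrays, and 329 to 940 without 1. Starvation counts: 4130 in controls and 4463 in mutants without the dimmest 40%, where fewer are tested, and 3364 and 4222 at 1.5-fold. Difference of responses (250): 26 with the series matrix (27 on the dChip probe sets), 1208 and 1126 with the weights, 800 without the 2 arrays, and 81 to 549 without 1. Fewer arrays lower power, yet leaving out control fed replicate 3 or mutant starved replicate 2 raised it, and the cause of the gap to the series matrix was not tested. Hnf4 in fed larvae was called in the series matrix alone (log2 1.13, adjusted p = 0.00447, or 0.00235 on the dChip probe sets; 0.0863 to 0.405 elsewhere). The correlation of the genotype differences (0.179) was 0.127 with the series matrix, 0.201 without dim probe sets and 0.142 to 0.200 without 1 array; that of the fed genotype difference with the control starvation response (-0.0407) was 0.178 with the series matrix and -0.0811 to 0.0876 without 1 array, and the cause was not tested. Pairing by replicate number was not assumed and cannot be excluded. Of 18 same-numbered pairs 5 deviated together at r over 0.1 (range -0.40 to 0.28), and 2 of 12 arrays deviated most alike with one of their number. The dChip column names, however, run through the 4 groups within each replicate number. With the replicate block the counts were 74, 610, 6632, 7354 and 132. The block ended the call of 3 of 28 genes named for fed larvae, 2 of 48 for starved larvae and 9 of 30 for the difference of responses. The share of higher calls moved by over 10 points in these cases: fed genotype (17.6%) 31.7% with the series matrix, 29.2% on its dChip probe sets, 30.0% and 29.0% without control fed replicates 1 and 3 and 29.1% without the 2 arrays; starved genotype (51.4%) 38.7% at 1.5-fold; starvation (52.9% in controls, 49.5% in mutants) 64.6% and 61.3% with the series matrix; difference of responses (70.4%) 59.8% with median centring, 54.3% and 55.1% with the weights, 54.1% without the 2 arrays, 80.8% and 59.2% without control fed replicate 2 and control starved replicate 2, and 268 of 447 without mutant starved replicate 2. The median of all probe sets moved by 0.106 and 0.101 in the series matrix for starvation in controls and mutants, by 0.128 and 0.167 on its dChip probe sets, and by -0.128 with median centring in mutants. Signal over background limits the series matrix, where 19.9% of values lay under the floor.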

Other observations

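Members of other lists changed with starvation, in a comparison that called 68.2% of all probe sets in controls and 75.7% in mutants. Of 16 lipid carriers 6 rose and 5 fell in controls, among them the lipophorin receptor LpR1 (log2 1.48 ± 0.11) and the transfer protein gene Mtp (-1.30 ± 0.13), and 7 rose and 7 fell in mutants. Of 9 glycolysis transcripts 1, Hex-A (log2 1.06 ± 0.11), rose and 6 fell in controls, and 1 rose and 3 fell in mutants. Of 38 ribosomal protein transcripts 8 rose and 1 fell in controls (5 and 1 in mutants), and of 11 ribosome biogenesis transcripts 1 rose and 3 fell (1 and 7 in mutants). Of 24 digestive proteases 8 rose and 4 fell in controls and 3 rose and 8 fell in mutants. Of 8 heat shock proteins 1 rose and 4 fell in controls, with Hsp68 at log2 -1.79 ± 0.26, although the list's median turned from -0.268 to 0.215 in the series matrix, as did that of acyl-CoA synthetases (-0.098 to 0.272), ecdysone response (-0.236 to 0.067) and, downwards, amino acid catabolism (0.045 to -0.238). Of 11 acyl-CoA synthetases 4 rose and 3 fell in controls, with pdgy at log2 2.07 ± 0.14 and CG4830 at -4.05 ± 0.38. In the set test these 7 lists were not called (adjusted p = 0.25 to 0.99 in controls and 0.21 to 0.85 in mutants), although the series matrix called glycolysis lower in controls (0.042) and ribosome biogenesis lower (0.025) and ribosomal proteins higher (0.037) in mutants, and quantile normalization called ribosomal proteins higher in both (0.013 and 0.042). None of these held with the correlation estimated in the same values, a setting chosen after seeing the data (adjusted p = 0.57 to 0.91). Further large falls were those of AANATL4 (log2 -4.55 ± 0.42), CG8012 (-4.29 ± 0.25) and CG3348 (-4.18 ± 0.25) in controls, where the starved values of AANATL4 and CG8012 lie under the lowest array's 25th percentile, so the sizes of their falls are uncertain.

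Markers of other tissues and stages were compared between genotypes. Of 9 hemocyte markers 3 fell in starved mutants (8 when adjusted over the list alone, median log2 -0.505), and of 8 male germline markers 1 fell (5 when adjusted over the list alone, median -0.573). Of 13 ecdysone response transcripts 0 were called in fed and 1 (higher) in starved mutants, and 4 rose and 6 fell with starvation in controls. Of 8 L3 staging transcripts 0 were called in either genotype comparison, and 3 rose and 1 fell in starved controls. Of 9 muscle markers 0, of 7 neuronal and glial markers 1 (Gs2, lower), and of 7 oenocyte and Malpighian tubule markers 1 (lower) were called in starved mutants, against 0, 0 and 1 (lower, and 1 higher and 2 lower when adjusted over the list alone) in fed mutants, and 6 tricarboxylic acid cycle transcripts gave 0 calls in both genotype comparisons. Ecdysone response, staging, muscle, neuronal, oenocyte and tricarboxylic acid cycle lists had an adjusted p of 0.22 or more in the set tests of genotype, but the series matrix called muscle markers lower in fed mutants (0.022, but 0.56 with an estimated correlation). Carbohydrases gave 1 lower call of 16 in fed and 1 higher and 1 lower in starved mutants, and amino acid catabolism 0 calls of 16 in fed and 1 higher and 1 lower in starved mutants.

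In fed larvae the gluconeogenesis list (0 of 9 called), lipases (0 of 15), lipogenesis (0 of 14), autophagy (0 of 14), the respiratory chain (0 of 56), cuticle proteins (0 of 75), antimicrobial peptides (0 of 21), hemocyte markers (0 of 9) and P450s (1 higher and 1 lower of 63) were not called as sets between genotypes, with 1071 probe sets at an unadjusted p under 0.05 and 102 past the adjusted threshold in limma. The series matrix called 6 further lists lower there: ribosomal proteins (adjusted p = 4.9e-05), the respiratory chain (0.00028), glycolysis (0.00029), muscle markers (0.022), lipogenesis (0.03) and acyl-CoA synthetases (0.036). Quantile normalization called glycolysis as well (0.03), and without the 2 low-weight arrays lipases (1.2e-05), carbohydrases (0.0055) and acyl-CoA synthetases (0.0095) were called lower and cuticle proteins (0.018) higher. With the correlation estimated in the same values, a setting chosen after seeing the data, none of these calls held (adjusted p = 0.27 to 0.76). The genes CG13284 (log2 0.81 ± 0.13) and CG17560 (0.79 ± 0.15) completed the 8 largest rises there.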
